A study of Homo sapiens with 6 samples.

How the data were processed

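Total RNA from 6 HUVEC samples, 3 with vehicle and 3 with simvastatin at 10 µM, was extracted with Qiagen's miRNeasy kit and labelled with Cy3 for Illumina microRNA arrays, per the labels' protocols. The protocol gives an exposure of 24 hours. The groups and replicate numbers were taken from the sample titles. The arrays were read out in GenomeStudio, per the submitters' processing notes, and its version is not given in the sources used here.

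The authors deposited 2 tables of 1145 probes. The first holds, per the file headers, the average bead signal of each probe as an intensity on a linear scale, without normalization, and a detection p-value for each signal. The deposited detection p-values follow the upper tail of a normal distribution around a background mean and SD of each array, to within 16.1 intensity units, and are cut off at 3.68e-38. The fitted background SD was 42.8 to 69.8 units. The second table holds scaled intensity values that the authors made from the first. On each array they equal the raw signal minus a constant (353 to 411 units), times a factor of 0.767 to 0.993, to within 0.00677 units. This gave every array a mean of 3474. Scale (linear), centring and direction are thus known from the values, although no label states these steps. The medians of this table were 298, 212 and 269 for controls 1, 2 and 3, and 254, 255 and 221 for simvastatin 1, 2 and 3. Between 148 and 195 values per array were negative. A change shared by all microRNAs cannot be seen in this second table, whose arrays all have the same mean, nor in the raw signals once their distributions are made equal.

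Raw signals were processed here with neqc of limma 3.58.1 in R 4.3.3. It fits the background from the detection p-values, corrects by the normexp model, adds an offset of 16, makes the arrays' distributions equal by quantile normalization and takes log2. Fold changes of dim probes are understated by the offset. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept whatever their group, which left 764 probes, of which 700 were detected on all 6 arrays. The 381 probes left out included 297 detected on no array. Simvastatin was compared with control by lmFit and eBayes over all 6 arrays with no covariate, as a two-sided test with Benjamini-Hochberg adjustment over the 764 probes and a threshold of 0.05. Array-level values were compared by exact permutation over the 20 assignments of 6 arrays to groups, for which 0.1 is the smallest two-sided p. The precision of all values is limited by the number of arrays.

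The test was run on simulated arrays with the probe levels and background of these arrays and, for the spread of each probe, either its sample SD or the SD moderated by limma. With the sample SDs, which were simulated first, 12.7% of calls were false with 40 changed probes and 12.3% with 200, above the 5% aimed at. The moderated SDs, taken up after that result was seen, fit the model of the test better and gave lower shares. With them and 40 changed probes among a mean of 807 tested, in 20 simulated sets, 33.0% of 1.5-fold, 60.5% of 2-fold and 77.6% of 3-fold changes were found, and 6.84% of calls were false. With 200 changed probes the shares found were 49.9%, 76.6% and 88.3%, and 8.55% of calls were false. Without the step between arrays, 4.83% of calls were false with 200 changed probes. The simulated arrays held no difference in overall brightness for that step to remove, so its effect on the real arrays cannot be judged from this. Given the simulated shares above 5% with that step, the share of false calls among the changed probes may exceed the threshold. In the simulation, background noise was added to spreads that already held it, and noise was drawn separately for each probe. The real arrays shared deviations across probes, so the simulated shares may differ from those on the real arrays.

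The design, the alternatives and the rule for named probes were fixed before the data were examined. The plan held 17 lists of microRNAs, a class of passenger strands and a panel of 17 named microRNAs. None of these could be tested, since no table used here pairs the probe identifiers with microRNA names. Markers of other cell types could not be checked for the same reason. The rule for named probes takes those with the largest log2 change among probes past the threshold whose groups do not overlap, here limited to 2 rises and 2 falls by identifier. Probes for members of 1 microRNA family can share signal by cross-hybridisation, which could not be assessed.

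Same-numbered samples were checked for pairing by correlating their deviations from the group means over the 764 probes. The correlations were -0.34, 0.38 and -0.46 for numbers 1, 2 and 3, and the main fit did not pair the samples. This check could not exclude pairing. Deviations cancel out within each group, and those of control 3 and simvastatin 1 correlated at 0.643. That pulls the correlations for numbers 1 and 3 down. Alternatives were other background corrections and normalizations, the deposited scaled table (values under 16 set to 16, which affected 2 values of kept probes, then log2), other filters, another variance model, the replicate number as a block and leaving out each array.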

Results

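MicroRNA levels were measured in human umbilical vein endothelial cells (HUVECs), primary cells that line the vein of the umbilical cord, after exposure to simvastatin or to its vehicle. Simvastatin inhibits HMG-CoA reductase, the rate-limiting enzyme of cholesterol synthesis, and the vehicle was dimethyl sulfoxide (DMSO). The simvastatin group received 10 µM for 24 hours. Each group held 3 samples, and each sample was hybridised to 1 single-colour Illumina microRNA array carrying 1145 probes. The question posed by the series title is which microRNAs the statin regulates in these cells. Nothing in the labels says whether the 3 samples of a group came from separate cultures or donors, so the p-values measure the spread between these samples, which may be technical. Neither the deposited tables nor the reference used here pair the probes with microRNA names, so probes are given by their identifiers.

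The median raw signal over all 1145 probes was 765, 587 and 739 intensity units in controls 1, 2 and 3 and 740, 708 and 576 in simvastatin 1, 2 and 3. The background mean recovered from the detection p-values lay between 353 and 411 units per array, and the median probe kept for testing was 3.53 to 4.60 times as bright as that background. No pair of arrays held identical values. Over the 764 probes kept, arrays of 1 group correlated at r = 0.977 to 0.993 across probes and arrays of different groups at r = 0.972 to 0.990, where probes are not independent replicates. The first principal component held 42.9% of the variance and did not separate the groups, since control 3 (score 9.94) and simvastatin 1 (3.71) lay at its upper end. The second component, with 30.7%, ran from control 1 (9.13) and control 2 (2.80) through control 3 (-0.74) to the 3 simvastatin arrays (-2.48 to -4.57). On both control 3 and simvastatin 1, 8 probes were at least 2-fold brighter than on each of the other 4 arrays, and 0 were at least 2-fold dimmer. For the other pairs of a control and a simvastatin array both numbers were 0.

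**Figure D1:**
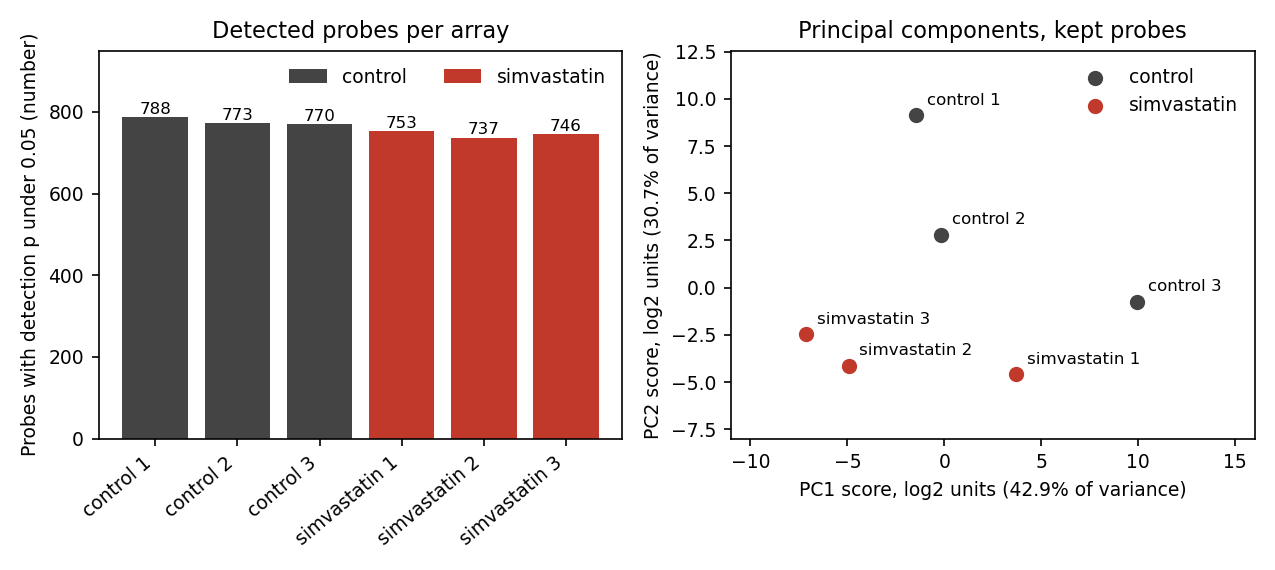
Left, number of probes with a detection p under 0.05 on each of the 6 arrays (bars, axis from 0), 770 to 788 in controls and 737 to 753 with simvastatin. Right, scores of the 6 arrays on the first 2 principal components (log2 units) over the 764 probes kept, where PC1 (42.9% of variance) does not part the groups and PC2 (30.7%) places all 3 controls above all 3 simvastatin arrays.

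Fewer microRNA probes were detected on the simvastatin arrays. At a detection p under 0.05, 788, 773 and 770 probes were detected in controls 1, 2 and 3, or 777 ± 9.64 (SD, n = 3). The simvastatin arrays detected 753, 737 and 746 probes, or 745 ± 8.02 (SD, n = 3). The groups did not overlap, and the difference of simvastatin minus control was -31.7 probes, with a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 can reach. The counts also ran with position on the chip, with a slope of -6.25 probes per array within groups and a group difference of -10.6 per array. The overall brightness of the probes differed little. The log2 median raw signal of the 764 kept probes was 10.62 ± 0.30 (SD, n = 3) in controls and 10.64 ± 0.29 (SD, n = 3) with simvastatin, with a two-sided exact permutation p of 0.9. The background mean was 390 ± 30.4 (SD, n = 3) units in controls and 386 ± 28.8 (SD, n = 3) with simvastatin (two-sided exact permutation p = 0.7).

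Of the 764 probes kept, 39 (5.10%) differed between simvastatin and vehicle, and of these 29 rose and 10 fell (limma's moderated test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small. Of the rising probes, 8 changed at least 2-fold, 12 between 1.5-fold and 2-fold, and 9 by less than 1.5-fold. Of the falling probes, 2 changed at least 2-fold, 3 between 1.5-fold and 2-fold, and 5 by less than 1.5-fold. The median change was 1.65-fold among the rising probes (range 1.19-fold to 2.77-fold) and 1.51-fold among the falling ones (range 1.29-fold to 4.29-fold). The 2 groups of arrays did not overlap for any of the 39, and 37 of them were detected on all 6 arrays. A further 10 probes were at least 2-fold lower with simvastatin in the group means without passing the test, and the SD within at least 1 group exceeded 1 log2 unit for 7 of them. An unadjusted p under 0.05 was reached by 136 probes, where 38.2 are expected by chance, and the groups did not overlap for 183 probes (24.0%), where chance gives 10%. With cyclic loess in place of quantile normalization 17 of 27 changed probes rose (63.0%), against 29 of 39 (74.4%) here.

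The deepest change was a fall. Probe ILMN_3168885 dropped from a normalized log2 signal of 13.05 ± 0.14 (SD, n = 3) in controls to 10.95 ± 0.28 (SD, n = 3) with simvastatin, 4.29-fold lower (95% confidence interval 3.24 to 5.67). Its log2 change was -2.10 with a standard error of 0.16 (limma adjusted p = 0.00496). The raw signal of this probe was 10123, 6846 and 9476 units in the controls and 3066, 2673 and 1553 in the simvastatin arrays, so the groups were apart before any normalization. The second largest fall among the probes that passed the test was that of ILMN_3168650, from 11.75 ± 0.25 to 10.17 ± 0.22 (SD, n = 3 each). This was 2.99-fold lower (95% confidence interval 2.22 to 4.02; limma adjusted p = 0.0118). Its adjusted p was 0.0505 without control 3, 0.0611 without simvastatin 1 and 0.0860 without simvastatin 2, with log2 changes of -1.50, -1.51 and -1.52.

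The 2 largest rises were of nearly equal size. ILMN_3167703 rose 2.77-fold (95% confidence interval 2.29 to 3.35), from 9.05 ± 0.07 in controls to 10.52 ± 0.19 with simvastatin (normalized log2 signal, SD, n = 3 each). ILMN_3167240 rose 2.76-fold (95% confidence interval 2.31 to 3.30), from 8.60 ± 0.15 to 10.06 ± 0.11 (SD, n = 3 each). Both had a limma adjusted p of 0.00496 and were detected on all 6 arrays. Both remained under the threshold when any 1 array was left out. Their raw signals were moderate, at 918 ± 111 (SD, n = 3) units in controls and 1899 ± 526 (SD, n = 3) with simvastatin for ILMN_3167703, and 776 ± 113 and 1444 ± 342 (SD, n = 3 each) for ILMN_3167240. The control level of the falling ILMN_3168885 was 8815 ± 1736 (SD, n = 3) units. Levels of different probes are not compared, since each probe has its own response.

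**Figure D2:**
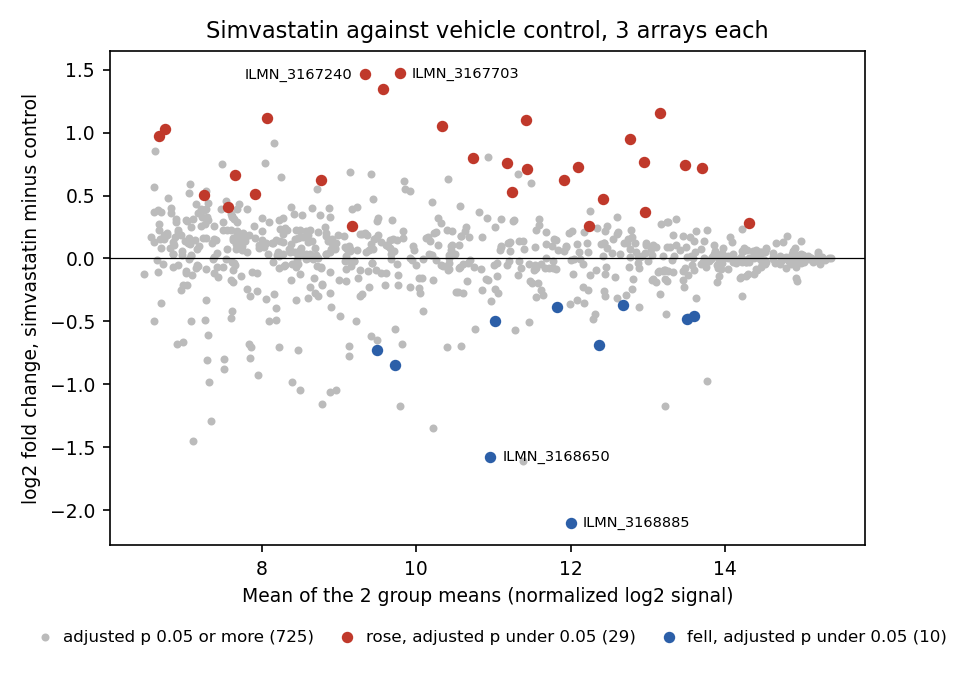
Each point is 1 of the 764 probes kept, with the mean of the 2 group means on the x axis (normalized log2 signal) and the log2 fold change of simvastatin over vehicle control on the y axis. Red points (29) rose and blue points (10) fell at an adjusted p under 0.05, and the named falling probe ILMN_3168885 at -2.10 lies farthest from 0 among the changed probes.

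**Figure D3:**
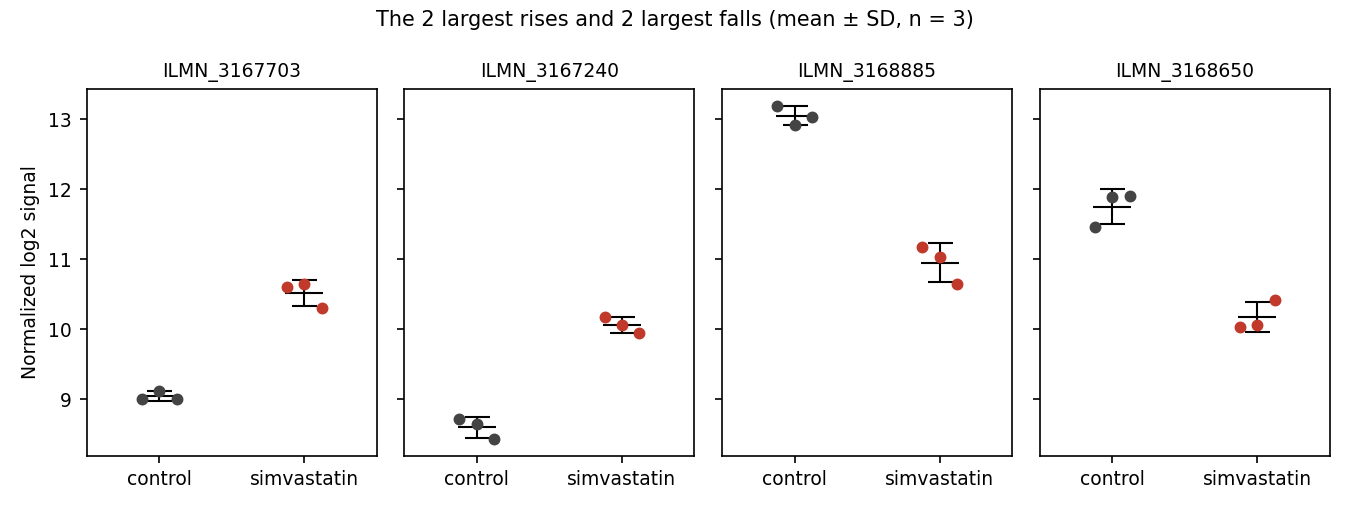
Normalized log2 signal of the 2 probes with the largest rise and the 2 with the largest fall among those that passed the test, as 1 point per array with the mean and SD of each group (n = 3; the y axis is shared and does not start at 0). In each panel the 3 simvastatin arrays lie apart from the 3 controls, by 1.47 (ILMN_3167703), 1.46 (ILMN_3167240), -2.10 (ILMN_3168885) and -1.58 (ILMN_3168650) in the mean.

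The number of changed probes depended on single arrays. Leaving out control 1, 2 or 3 left 12, 17 or 13 changed probes, and leaving out simvastatin 1, 2 or 3 left 11, 10 or 18. The same 10 probes, 9 of which rose, were called in each of these 6 fits. All 39 kept an unadjusted limma p under 0.05 in each, which is no separate support since these same arrays picked them. Their direction could not reverse there, since the groups did not overlap for any of the 39. Without control 3 and simvastatin 1 together, a choice made after seeing the data, limma called 0 probes, the smallest adjusted p was 0.101, and 110 probes had an unadjusted p under 0.05. With 2 arrays per group in that fit, the log2 changes were 1.41 for ILMN_3167703, 1.32 for ILMN_3167240, -2.22 for ILMN_3168885 and -1.44 for ILMN_3168650, against 1.47, 1.46, -2.10 and -1.58 with all arrays. With limma's array weights, also chosen after seeing the data, 79 probes were called, and the weights ranged from 0.375 for simvastatin 3 and 0.429 for control 1 to 3.23 for simvastatin 2. All 6 arrays lay on 1 chip, with the controls in the first 3 of the positions used and the simvastatin samples in the last 3, so that position and treatment cannot be told apart by design.

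Few probes were detected in one group alone. With simvastatin, 3 probes passed the detection threshold on all 3 arrays and on none of the control arrays, and 2 of these were among the 29 that rose. For those 2 the control level on each array was taken as the higher of the probe's own signal and the lowest detected signal. The group means were then 1.48-fold (ILMN_3168084) and 1.60-fold (ILMN_3168305) higher with simvastatin. These are not lower limits, since the 95% confidence interval of ILMN_3168305 in the main fit began at 1.54-fold. Raw signals were low, at 446 ± 43.9 units in controls and 512 ± 56.8 with simvastatin for ILMN_3168084 (SD, n = 3 each). For ILMN_3168305 they were 455 ± 56.6 and 523 ± 20.1 (SD, n = 3 each), where the background SD was 42.8 to 69.8 units per array. The third of the 3 probes did not pass the test (limma adjusted p = 0.0711). In the controls 1 probe was detected on all 3 arrays and on no simvastatin array, and its change did not pass the test (limma adjusted p = 0.368). At a detection p under 0.01 the numbers were 0 for simvastatin and 3 for controls, so these counts depend on the threshold.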

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

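Leaving out control 3 and simvastatin 1 together and fitting array weights were chosen after seeing the data; the other settings were planned. All 39 changed probes kept their direction with each other background correction, normalization and source table. The remaining settings could not test direction. Other filters, the variance model and the block leave the log2 changes as they were. Leaving out or weighting arrays cannot reverse groups that do not overlap. Of the 39, 9 (7 rising) were called in each of the 9 planned settings of background, normalization, source table, filter and variance model. The count, 39 (29 rose, 10 fell), was 18 (13 and 5) with median scaling, 27 (17 and 10) with cyclic loess, 15 (11 and 4) in the deposited scaled table and 21 (14 and 7) with no filter, which tests 1145 probes. It was 51 (32 and 19) with a trended robust variance, 79 (54 and 25) with array weights, and 0 (0 and 0) without control 3 and simvastatin 1, where 2 arrays remain per group. It was 35 (24 and 11) without background correction, 38 (27 and 11) with normexp at offset 50, and 39 (28 and 11) with either stricter filter. Leaving out 1 array gave 10 to 18 changed probes, 9 to 14 rising and 1 to 4 falling. With the replicate number as a block 1 probe was called (1 rose, 0 fell). In that fit 32 had a limma adjusted p under 0.1. All 39 kept an unadjusted limma p under 0.05, though they were picked on these same arrays. The fit has fewer degrees of freedom, and the labels do not say whether the numbers pair the samples. Over 18 alternatives the adjusted p of the named probes ranged from 0.000457 to 0.101 (ILMN_3167703 and ILMN_3167240), 0.000125 to 0.101 (ILMN_3168885) and 0.000518 to 0.133 (ILMN_3168650). The difference in detected probes, -31.7, was -26.7 at a detection p under 0.01. With 1 array left out it could not reverse, since the groups did not overlap. The difference in log2 raw signal, 0.017, turned to -0.0049 at a detection p under 0.01 and, with 1 array left out, ranged from -0.148 to 0.185. Probes detected in 1 group alone numbered 3 for simvastatin and 1 for control, and 0 and 3 at a detection p under 0.01. With 1 array left out they numbered 3 to 4 for simvastatin and 2 to 10 for control. Leaving out an array loosens the rule, so those counts could only stay or rise. The cause of these shifts was not tested where not named. The lists and the passenger strand class were not run, for want of probe names. Signal over background limits the dim probes: 29.2% to 35.2% of kept probes lay under 2 times the background.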

Other observations

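The tests of other splits, of chip position, of exchanged labels, of another RNA source and of the rises without background correction, and the view of probes by level, were chosen after the results they bear on had been seen. For chip position, ratios over all probes and by the size of the difference came first, and the probes called with a slope fitted were taken after those.

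The changed probes were spread over the range of signal levels. The 764 probes kept were ranked by mean normalized signal and divided into 3 parts. The dimmest part (255 probes) held 7 changed probes, all of which rose. The middle part (254) held 18, of which 12 rose and 6 fell, and the brightest part (255) held 14, of which 10 rose and 4 fell. Differences between the parts did not pass the threshold for the share of rising probes (two-sided Fisher's exact test, p = 0.482, adjusted 0.482). Nor did they in the same exact test, after Benjamini-Hochberg adjustment over 3 tests, for the share of falling probes (p = 0.0283, adjusted 0.0848) or of all changed probes (p = 0.0683, adjusted 0.103).

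Probe ILMN_3168485, chosen after its values were seen, was among the 8 probes at least 2-fold brighter on both control 3 and simvastatin 1 than on each of the other 4 arrays. Its raw signal was 9949 units on control 3 and 4937 on simvastatin 1. On control 1, control 2, simvastatin 2 and simvastatin 3 it was 1557, 918, 737 and 596 units. None of the 8 passed the test for simvastatin, and for 6 of them controls 1 and 2 both lay above simvastatin 2 and 3.

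Control 3 and simvastatin 1 departed from their groups in the same direction, with a correlation of 0.643 between their deviations over the 764 probes. Exchanged labels gave 0 changed probes in place of 39. This argues against an exchange only if the 39 come from treatment and not from a step in chip position. A correlation of 0.553 in the brightest part argues against noise of dim probes. One of 0.663 with median scaling argues against quantile normalization. A candidate explanation is RNA of another source in both samples at different amounts: over 15 probes at least 2-fold above the other 4 arrays on control 3, the excess on simvastatin 1 was a median 0.363 of that on control 3 (range 0.024 to 0.772), with 12 of the 15 within 2-fold of the median. A culture state or cell lot shared by those samples could give the same picture and stays open. No biological explanation was tested, since no group in the labels joins these samples.

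Of the 10 splits of the 6 arrays into 3 and 3, only the real one gave as many as 39 changed probes. The highest count of the others was 0. Each of the others mixes control and simvastatin arrays, so a group difference counts as spread in it and lowers its count. An unadjusted limma p under 0.05 was reached by 136 probes in the real split and by 5 to 56 in the others. Since 10 splits are also too few for a share under 0.05, no conclusion on chance is drawn. Position on the chip runs with treatment, and a steady gradient as the whole source would make the slope along the chip within groups equal to that between them, a ratio of 1, where the ratio was 0.272 over all 764 probes (95% bootstrap interval over probes 0.163 to 0.385), 0.092 (-0.093 to 0.268) over the 20 at least 2-fold apart in the mean and 0.381 (0.249 to 0.525) over the other 744, which noise and the choice of probes pull down. The 29 probes that limma called with a slope within groups in the fit, 27 of them among the 39, are picked independently of that slope, and their ratio of 0.0086 (-0.128 to 0.149 over probes, which leaves out the error shared within an array, and -0.113 to 0.130 over 1 score per array), -0.035 in controls alone, 0.052 in simvastatin arrays alone and -0.0015 without control 3 and simvastatin 1, argues against a steady gradient as their whole source. For the other 12 the ratio was 0.099 (-0.054 to 0.214), but they were called only where a slope counts as noise, so for them a gradient cannot be told apart from an effect of simvastatin. A step between the first and the last positions was not tested and stays open for all 39, beside the effect of simvastatin that the design names.

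Rises made up 74.4% of the changed probes (exact 95% interval 57.9% to 87.0%). Of the 20 probes at least 2-fold apart in the mean, 8 were higher and 12 lower with simvastatin, and 10 of those 12 missed the threshold. The SD within at least 1 group exceeded 1 log2 unit for 7 of those 10, so the direction of an effect is uncertain for those 7. The other 2 of the 12 passed the test as falls. These 20 probes thus do not settle whether rises or falls prevail. Without background correction 24 of 35 changed probes rose, or 68.6% (50.7% to 83.1%), which argues against that step as the source of the excess, though by little, since the interval takes probes as independent. Among changed probes over 2 times the background 22 of 32 rose, or 68.8% (49.99% to 83.9%). This test was fixed beforehand, and its interval just reaches an even split, so it does not argue against background correction of dim probes as the source. With median scaling in place of quantile normalization 13 of 18 rose, or 72.2% (46.5% to 90.3%), an interval that reaches an even split, so normalization cannot be told apart from an effect of simvastatin as the source.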
